A study of Mus musculus with 6 samples.

How the data were processed

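Total RNA from 6 samples of BCR-ABL1-transformed mouse pre-B cells (strain 129P2/OlaHsd) was labelled with biotin and hybridised to Affymetrix gene arrays, per the labels' protocols. The cells were resistant to puromycin and RNA was extracted after 2 days in 0.5 micromolar of the tamoxifen metabolite. Groups were taken from the sample labels, with 3 arrays labelled ERT2 (vector without Cre) and 3 labelled CRE-ERT2, and replicate numbers 1 to 3 were taken from the same labels. The table deposited by the authors holds 1 log2 expression value per probe set and array. RMA, a method that corrects background, normalizes between arrays and summarises probes, and Partek 6.5 are named in the submitters' processing notes, without role or order. That the values are on a log2 scale was read from their range, since no sentence of the labels states it. Scanner output, detection calls and scan dates were not used here, so signal over background is unknown, the change of a gene near background is compressed, and batches could not be tested.

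The table has 35556 probe sets. The platform annotation lists exactly 1 gene for 21789 of them, several for 1621 and none for 12146. Entrez identifiers of 21698 single-gene probe sets were found in a gene table of the mouse assembly GRCm38.p6, and 0 symbols changed through it. The assembly behind the array design is not given in the sources used here, so no coordinates are printed. Probe sets with several genes or with none were left out of the gene tests. For the 999 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was kept, which left 19938 genes. The arrays were not filtered for dim probe sets and were not normalized again. No pair of arrays was a duplicate: identical values occurred in 8 to 57 of the probe sets of a pair, and Pearson correlations over probe sets were 0.991 to 0.996, within and between groups.

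The arrays labelled CRE-ERT2 were compared with those labelled ERT2 by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the group as the only term. Values of p were adjusted over all genes by the Benjamini-Hochberg method, with a threshold of 0.05 and no minimum change. The labels do not say that the samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The median within-group SD over genes was 0.0973 on the log2 scale. Ptpn6 was also compared by a two-sided exact permutation test. Gene lists were compared with all other genes by limma's camera with its preset correlation of 0.01, adjusted over 28 lists, and again with a correlation estimated per list. Each list member was also adjusted over the list alone. The lists hold 628 names, of which 574 are measured, for 558 distinct genes, since some genes stand in more than 1 list. List names were matched by current symbol or by an unambiguous synonym, and members with no single-gene probe set were not analysed here.

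The samples, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Ptpn6, then the 12 genes with the largest increase and the 12 with the largest decrease among those that passed and whose groups did not overlap, and then up to 4 passing members of each list with the largest change. Where fewer than 2 members of a list passed, members with the smallest p were added up to 2, as values. Predicted genes without a proper symbol, olfactory and vomeronasal receptor genes and antigen receptor segments were passed over among the 24 most changed genes, which removed 2 unnamed cDNA clones and 1 sequence known only by its database entry, all 3 of them higher.

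The fit and the list test were tested on simulated data before use. There were 10 simulated data sets of 19938 genes. The spread of each gene was the SD that eBayes gave it, which is drawn towards that of other genes. In each set 200 genes were changed by known amounts for the CRE-ERT2 against ERT2 comparison. Of the changed genes, 40.2% were called at a log2 change of 0.3, 97.8% at 0.5 and 100% at 1 and at 2, and 6.34% of called genes were unchanged. A list shifted by 0.2 was called in 10 of 10 runs, and 0 of 253 unshifted lists were called. The simulated genes varied independently, so these values do not cover correlated lists. They also rest on the eBayes spreads and on 200 changed genes, where 914 passed in the real data, so the real rates may differ.

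The alternatives were a further quantile normalization, centring each array on its median, leaving out the dimmest genes (a share of 0.333), the mean of a gene's probe sets, testing all probe sets, a trended and robust variance, array weights, the replicate number as a block, a minimum log2 change of 1, and leaving out each array in turn. For lists they were also an estimated correlation, fry and camera on ranks. An alternative that leaves out genes belonging to more than 1 list was chosen after seeing the data.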

Results

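Gene expression was measured on 6 arrays of total RNA from mouse pre-B cells transformed with BCR-ABL1, the fusion kinase that drives Philadelphia chromosome-positive acute lymphoblastic leukaemia. According to the sample labels the cells carried 1 floxed and 1 unfloxed allele of Ptpn6, which encodes the tyrosine phosphatase SHP-1, a negative regulator of signalling from cell surface receptors. One group of 3 arrays came from cells transduced with an ERT2 vector, which carries the hormone-binding domain of a modified oestrogen receptor and no recombinase. The other group of 3 came from cells transduced with CRE-ERT2, in which that domain keeps the Cre recombinase inactive until tamoxifen is given. Both groups received 0.5 micromolar of the active tamoxifen metabolite for 2 days, so the vector was the only labelled difference, and the question was what Ptpn6 does in these leukaemia cells. Median log2 expression lay between 7.90 and 7.98 on the 6 arrays, and the number of arrays limits the precision of every comparison.

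Ptpn6 itself, the gene targeted by the floxed allele, did not differ between the groups by more than the spread between arrays. Its log2 expression was 11.34 ± 0.08 (SD, n = 3) in the arrays labelled ERT2 and 11.27 ± 0.08 (SD, n = 3) in those labelled CRE-ERT2. The difference was -0.07 with a standard error of 0.08 and a 95% confidence interval from -0.24 to 0.10, which is a ratio of 0.952 (0.848 to 1.07). The adjusted p was 0.759 with limma. A two-sided exact permutation test of the 6 values gave p = 0.3, where 3 arrays against 3 cannot go below 0.1. Ptpn6 was read by 1 probe set (10547769), and whether that probe set lies in the floxed part of the gene is not known here, so this level neither supports nor contradicts the labels. The groups are therefore called the arrays labelled ERT2 and the arrays labelled CRE-ERT2, and every direction below runs from the first to the second as labelled.

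**Figure D1:**
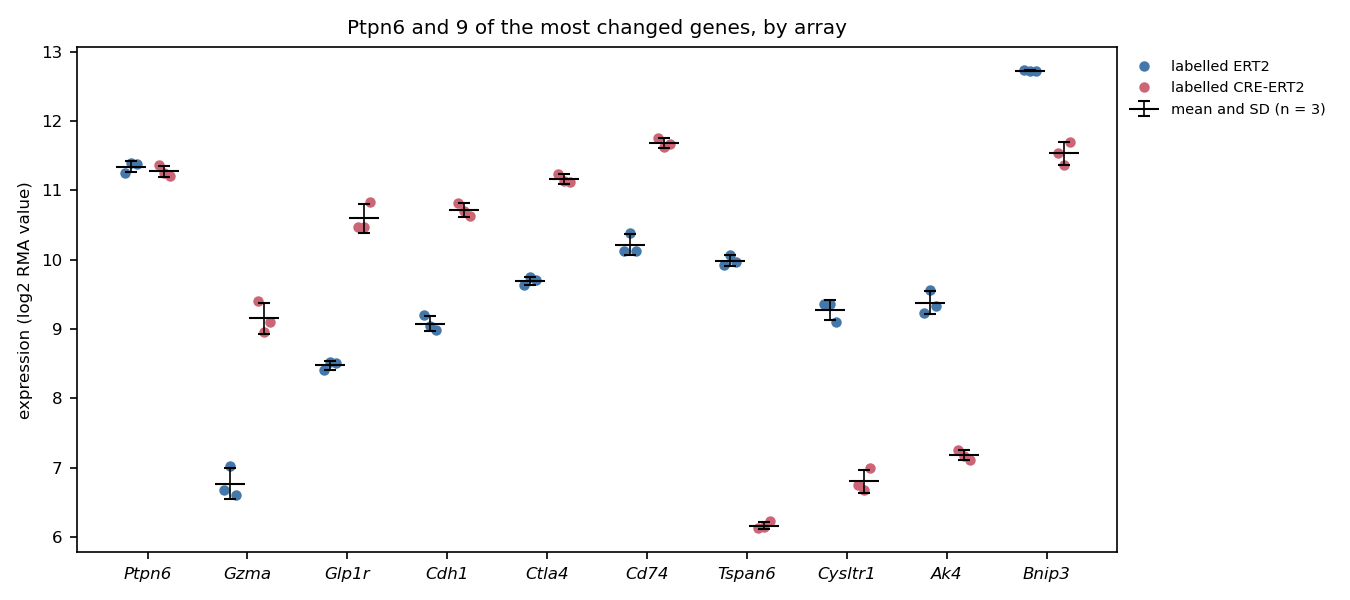
Log2 expression (vertical axis, log2 RMA values) of Ptpn6 and 9 of the most changed genes on each of the 6 arrays, with points for arrays, horizontal bars for group means and error bars for SD (n = 3 per group). The Ptpn6 means of 11.34 and 11.27 lie within the spread between arrays, while Tspan6 lies at 9.99 in the arrays labelled ERT2 and 6.17 in those labelled CRE-ERT2.

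The largest change was a fall of Tspan6, a tetraspanin membrane protein, from 9.99 ± 0.08 to 6.17 ± 0.06 (SD, n = 3 each), which was 14.1-fold (limma adjusted p = 1.28e-11). Cysltr1, the receptor for cysteinyl leukotrienes, fell 5.53-fold (log2 change -2.47). Ak4, a mitochondrial adenylate kinase, fell 4.60-fold (-2.20) on the probe set kept, and less on a second one given below. Bnip3, which takes part in the removal of mitochondria, fell 2.28-fold (-1.19). Gzma, the granule protease granzyme A, showed the largest increase, from 6.77 ± 0.22 to 9.15 ± 0.22 (SD, n = 3 each), which was 5.21-fold (adjusted p = 2.51e-07). Glp1r, the receptor for an incretin hormone, rose 4.33-fold (2.12) and Cdh1, which encodes the adhesion protein E-cadherin, rose 3.12-fold (1.64).

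Ctla4, an inhibitory receptor best known from T cells, and Cd74, the invariant chain of MHC class II molecules, each rose 2.77-fold (log2 change 1.47). Csf1, the macrophage colony-stimulating factor, rose 2.52-fold (1.33), and Ly6f rose 3.54-fold (1.82). The prohormone-processing enzyme gene Cpe (1.56), the secreted protease gene Htra3 (1.43), the aryl hydrocarbon receptor repressor gene Ahrr (1.41), Cyyr1 (1.40) and the vesicular glutamate transporter gene Slc17a8 (1.26) completed the 12 largest increases. Among the 12 largest decreases were the metallothionein genes Mt2 (-1.56) and Mt1 (-1.37), the bone morphogenetic protein receptor gene Bmpr1a (-1.44), the surface receptor gene Slamf7 (-1.42) and Crhbp, which encodes a binding protein for corticotropin-releasing hormone (-1.30). The calcineurin regulator gene Rcan2 (-1.21), the lymphoid tyrosine phosphatase gene Ptpn22 (-1.21) and Ifi30, a lysosomal thiol reductase gene (-1.16), also fell. For all 24 of these genes the 3 arrays of one group lay wholly above the 3 of the other, and adjusted p was between 1.28e-11 and 0.000547 with limma. A second Ak4 probe set, with a mean level of 7.95 against 8.28 for the one kept, changed by -0.44. Its unadjusted p was 0.0473 with limma over all probe sets. A second Bnip3 probe set changed by -1.19. Ly6f, Mt1 and Mt2 have close paralogs whose transcripts these probe sets could in part read, and Mt2 did not pass when all probe sets were tested (adjusted p = 0.0660) or with a trended, robust variance (0.0506).

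Across 19938 genes tested, 914 (4.58%) differed between the groups with limma at an adjusted p under 0.05, of which 459 were higher and 455 lower in the arrays labelled CRE-ERT2. Most of these changes were small: the median absolute log2 change of the 914 genes was 0.42, or 1.34-fold, and 49 changed by at least 1 on the log2 scale (31 higher and 18 lower). The groups did not overlap for 4480 genes (22.5%), against the 10% that chance gives on average over all groupings of 3 against 3. This share was not computed for the other groupings, so how far a single one can lie from 10% is unknown. After a further quantile normalization the split moved to 60.9% higher among 892 genes, against 50.2% as deposited. With a trended, robust variance 1544 genes passed (957 lower), and with the dimmest genes left out 1260 (720 lower). The count fell to 560 (233 lower) without ERT2 replicate 1, to 574 (222 lower) without CRE-ERT2 replicate 2 and to 453 (286 higher, 167 lower) without CRE-ERT2 replicate 3. Without CRE-ERT2 replicate 1 it was 629 (288 higher). With the replicate number as a block it was 589 (326 higher, 263 lower), and 298 probe sets passed when all 35556 were tested.

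**Figure D2:**
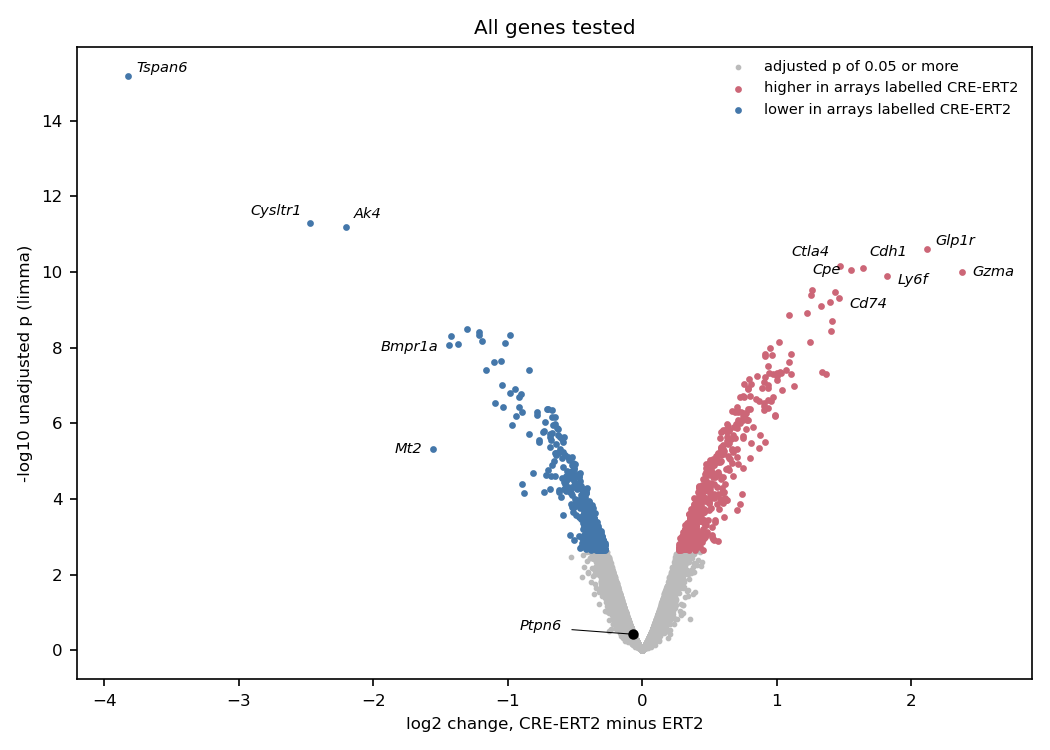
Log2 change (horizontal axis, arrays labelled CRE-ERT2 minus those labelled ERT2) against -log10 of the unadjusted limma p (vertical axis) for the 19938 genes, with the 459 higher genes in red, the 455 lower genes in blue and the others in grey. Tspan6 stands apart at -3.82, and Ptpn6 (black) lies near the centre at -0.07.

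Of the 28 gene lists fixed before the data were examined, 16 differed from the other genes with camera at its preset correlation, 9 higher and 7 lower in the arrays labelled CRE-ERT2. With a correlation estimated for each list, camera passed 0 of the 28 (lowest adjusted p = 0.0710, with 4 lists at an unadjusted p under 0.05), and fry, which asks whether the genes of a list move one way on balance, passed 12. The shifted lists that fry did not pass were the pre-B cell receptor (adjusted p = 0.0618), cholesterol synthesis (0.0806), ERK pathway (0.142) and DNA damage response (0.168) genes. The size of the estimated correlation alone did not account for the lost camera calls. For NF-kB target genes it was 0.0157, near the preset 0.01, yet camera's unadjusted p went from 5.45e-09 to 0.00507. For mature B cell genes it was -0.00973, below the preset, and camera's unadjusted p went from 0.00410 to 0.0360. What else differs between these settings of camera was not examined. A call lost with an estimated correlation is therefore not by itself a sign that correlated genes made the shift. Each shift below is given with camera's values at both correlations. Camera compares a list with the other genes and not with 0. The median log2 change of all genes tested was -0.03, so list medians near 0 are to be read against that value. Counts of members are over all genes tested unless they are said to be adjusted over the list alone, and members outside the naming rule that such a count adds were named after their values were seen.

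Interferon-stimulated genes, p53 target genes and NF-kB target genes were higher in the arrays labelled CRE-ERT2. Of 24 interferon-stimulated genes measured, 9 rose, 0 fell and 15 did not pass, and the median log2 change was 0.23. Rtp4, which encodes a receptor-transporting protein, rose by 1.02, the deISGylating protease gene Usp18 by 0.76, the nucleic acid sensor gene Zbp1 by 0.75 and Ddx58, which encodes the RNA sensor RIG-I, by 0.61. Adjusted over the list alone, 12 rose and 1, Ifit2 (-0.26, named here after its value was seen), fell. The list differed from other genes with camera (adjusted p = 2.76e-15), with adjusted p = 0.0710 with an estimated correlation. Of 25 p53 targets measured, 9 rose, 0 fell and 16 did not pass, with a median of 0.22. They included the polo-like kinase gene Plk2 (0.98), the stress-induced Sesn2 (0.59), the RNA-binding protein gene Zmat3 (0.55) and the receptor gene Eda2r (0.52). When adjusted over the list alone, 13 p53 targets rose. Camera gave an adjusted p of 3.59e-13, against adjusted p = 0.158 with an estimated correlation. The p53 targets Cdkn1a and Bax were not analysed here. Of 21 NF-kB target and activation genes, 7 rose, 0 fell and 14 did not pass, or 8 adjusted over the list alone. The costimulatory ligand gene Cd80 rose by 1.23 (0.42 on a second probe set), the cytokine gene Lta by 0.53, the stress gene Gadd45b by 0.49 and the chemokine gene Ccl3 by 0.46. The list had a median of 0.09 and an adjusted p of 3.82e-08 with camera, and adjusted p = 0.0710 with an estimated correlation. The call of Ccl3 was lost after a further quantile normalization (adjusted p = 0.0635). It was also lost without ERT2 replicate 1 (0.137), ERT2 replicate 3 (0.0591), CRE-ERT2 replicate 1 (0.0865) or CRE-ERT2 replicate 3 (0.0599). When all probe sets were tested, Sesn2 (limma adjusted p = 0.0684), Zmat3 (0.0577), Lta (0.0662), Gadd45b (0.0630) and Ccl3 (0.232) did not pass.

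Glycolysis genes were lower in the arrays labelled CRE-ERT2. Of 18 measured, 12 fell, 0 rose and 6 did not pass, with a median log2 change of -0.38. The phosphofructokinase genes Pfkl (-0.78) and Pfkp (-0.65), the aldolase gene Aldoc (-0.70) and the hexokinase gene Hk2 (-0.58) fell most. Once adjusted over the list alone, 13 fell. The camera adjusted p was 4.01e-11, and adjusted p = 0.273 with an estimated correlation, which was high in this list at 0.455. Of 23 oxidative phosphorylation genes, 0 passed in either direction, also when adjusted over the list alone. The 2 with the smallest p, the complex I genes Ndufs1 (-0.24) and Ndufv1 (0.18), went opposite ways, and the list was not shifted (camera adjusted p = 0.765).

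Targets of MYC, a transcription factor that drives growth and ribosome production, were also lower. Of 26 measured, 5 fell, 0 rose and 21 did not pass, with a median log2 change of -0.21. The 5 were the purine synthesis gene Ppat (-0.37), Myc itself (-0.35), the serine hydroxymethyltransferase gene Shmt1 (-0.33), the RNA polymerase I gene Polr1b (-0.31) and the lactate dehydrogenase gene Ldha (-0.30, named here after its value was seen). Adjusted over the list alone, 16 fell. Tested with camera, the list had an adjusted p of 8.26e-08, and adjusted p = 0.273 with an estimated correlation. The calls of Myc, Ppat, Shmt1 and Polr1b were lost without ERT2 replicate 1 (adjusted p = 0.129, 0.0730, 0.0607 and 0.0631), without CRE-ERT2 replicate 2 (0.0796, 0.0711, 0.0642 and 0.107) and without CRE-ERT2 replicate 3 (0.176, 0.0763, 0.125 and 0.152). Myc and Polr1b also lost theirs without ERT2 replicate 2 (0.0605 and 0.102), and Polr1b without CRE-ERT2 replicate 1 (0.0665) or with arrays centred on their medians (0.0502). With the replicate number as a block, Shmt1 (0.0710) and Polr1b (0.0920) did not pass. When all probe sets were tested, Myc (0.178), Ppat (0.115), Shmt1 (0.106) and Polr1b (0.131) did not pass.

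Genes of the integrated stress response, which the transcription factor ATF4 switches on when amino acids are short, were lower on balance. Of 24 measured, 7 fell, 1 rose and 16 did not pass, with a median log2 change of -0.14. The glutathione-degrading enzyme gene Chac1 (-0.88), the asparagine synthetase gene Asns (-0.67) and the mitochondrial folate enzyme gene Mthfd2 (-0.54) fell, and Sesn2 (0.59), also a p53 target, rose. The calls of Chac1 and Sesn2 were lost when all probe sets were tested (adjusted p = 0.130 and 0.0684). When adjusted over the list alone, 11 fell and 1 rose. Camera gave an adjusted p of 0.00448, and adjusted p = 0.349 with an estimated correlation. Genes of endoplasmic reticulum stress were not shifted (camera adjusted p = 0.329), and 0 of 20 passed, also when adjusted over the list alone. The lowest p belonged to the chaperone genes Creld2 (-0.17) and Dnajb11 (-0.16).

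Proliferation genes were slightly lower as groups, and no single member of the replication or mitosis lists passed in the main fit. Of 25 DNA replication genes, 0 passed, and 2 fell when adjusted over the list alone, Gins1 (-0.29) and Cdc6 (-0.26). The median was -0.15, and camera gave an adjusted p of 1.46e-05, with adjusted p = 0.349 with an estimated correlation. Of 25 mitosis genes, 0 passed, also when adjusted over the list alone. The lowest p belonged to the checkpoint kinase genes Bub1 (-0.30) and Ttk (-0.26). Gins1, Cdc6 and Bub1 passed with the dimmest genes left out (adjusted p = 0.0282, 0.0308 and 0.0323) and with a trended, robust variance (0.0173, 0.0293 and 0.00355), Gins1 and Cdc6 with array weights (0.0315 and 0.0407), Gins1 without CRE-ERT2 replicate 1 (0.0403) and Bub1 without ERT2 replicate 3 (0.0419). The median of the mitosis genes was -0.13, and camera gave an adjusted p of 0.00121, with adjusted p = 0.358 with an estimated correlation. Of 24 DNA damage response genes, Gadd45b (0.49) rose and the kinase gene Atr (-0.40) fell, and adjusted over the list alone 1 rose and 4 fell, adding Chek1 (-0.29), Fancd2 (-0.27) and Mre11a (-0.29). The median was -0.13, and camera gave an adjusted p of 0.0170, with adjusted p = 0.579 with an estimated correlation. That shift did not pass without ERT2 replicate 1 (adjusted p = 0.0977), ERT2 replicate 2 (0.0807) or CRE-ERT2 replicate 2 (0.0957), nor with the dimmest genes left out (0.0550), and Atr did not pass without ERT2 replicate 1 (0.0998), CRE-ERT2 replicate 1 (0.0506), CRE-ERT2 replicate 2 (0.107) or CRE-ERT2 replicate 3 (0.133).

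Of 16 cholesterol synthesis genes, 1 fell, the mevalonate kinase gene Mvk (-0.30), and adjusted over the list alone the lanosterol synthase gene Lss (-0.26) fell as well. The median was -0.12, and camera gave an adjusted p of 0.0155, with adjusted p = 0.433 with an estimated correlation. The shift did not pass without ERT2 replicate 2 (adjusted p = 0.149), CRE-ERT2 replicate 2 (0.0668) or CRE-ERT2 replicate 3 (0.0966), nor after a further quantile normalization (0.0613). Mvk lost its call whichever of the 6 arrays was left out, with adjusted p from 0.0528 without ERT2 replicate 1 to 0.190 without CRE-ERT2 replicate 3. Nor did Mvk pass after a further quantile normalization (0.0638) or centring (0.0652), with the replicate number as a block (0.111) or with all probe sets tested (0.156). Of 16 cyclin-dependent kinase inhibitor and senescence genes, 0 passed, also when adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.112, but 0.0276 on ranks). Lmnb1 (-0.22) and Cdkn2d (0.17) had the lowest p. Of 24 oxidative stress and NRF2 target genes, 0 passed, also when adjusted over the list alone (camera adjusted p = 0.618), and Gsr (-0.24) and Sod2 (-0.19) had the lowest p.

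Among BCL2 family genes and FOXO targets, more genes rose than fell. Of 14 regulators of the BCL2 family, 3 rose, the survival gene Bcl2 (0.79) and the death-promoting genes Bcl2l11 (0.44) and Bmf (0.39), 0 fell and 11 did not pass. Once adjusted over the list alone 4 rose and 2 fell, adding Bbc3 (0.26), Bid (-0.22) and Bok (-0.27). The median was 0.04, and camera gave an adjusted p of 0.00628, with adjusted p = 0.304 with an estimated correlation. The list did not pass on ranks (adjusted p = 0.0543) or without genes that other lists hold (0.138, an alternative chosen after seeing the data), and Bmf did not pass without CRE-ERT2 replicate 2 (0.0567) or CRE-ERT2 replicate 3 (0.0696). Of 23 FOXO target and quiescence genes, 6 rose, 3 fell and 14 did not pass, with a median of 0.12. The homing receptor gene Ccr7 (0.95), the repressor gene Klf3 (0.53) and Bcl2l11 rose. The recombinase gene Rag2 (-0.53) fell, as did Il7r (-0.43) and S1pr1 (-0.33), both named here after their values were seen. Adjusted over the list alone 7 rose and 3 fell. The camera adjusted p was 0.000553, with adjusted p = 0.304 with an estimated correlation.

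Of 18 STAT5 target genes, 3 rose, 1 fell and 14 did not pass, with a median log2 change of 0.07. The interleukin receptor gene Il2ra (0.63) and the feedback inhibitor genes Socs1 (0.45) and Cish (0.44) rose, and Myc (-0.35) fell. When adjusted over the list alone 4 rose, adding the kinase gene Pim2 (0.36), and 1 fell. Tested with camera, the list had an adjusted p of 0.000553, with adjusted p = 0.273 with an estimated correlation. Cish did not pass without CRE-ERT2 replicate 1 (adjusted p = 0.0628), and Myc is described with the MYC targets. Of 25 genes of ERK pathway feedback and immediate early response, 1 rose, the transcription factor gene Jun (0.67), also when adjusted over the list alone, and 0 fell. Of the 25 genes, 15 were higher and 10 lower. Etv5 had the next lowest p (-0.25), followed by Spred1 (-0.27) and Spry4 (-0.20), both named here after their values were seen. None of them passed. The median was 0.09, and camera gave an adjusted p of 0.00965, with adjusted p = 0.349 with an estimated correlation. That shift did not pass without ERT2 replicate 1 (0.0689) or CRE-ERT2 replicate 1 (0.136).

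Of 20 genes of the pre-B cell receptor and its proximal signalling, 0 passed, also when adjusted over the list alone, although 15 were higher. The kinase gene Pik3cd (0.23) and the adaptor gene Blnk (0.21) had the lowest p. The median was 0.07, and camera gave an adjusted p of 0.00762, with adjusted p = 0.304 with an estimated correlation and 0.0780 without CRE-ERT2 replicate 1. Of 23 inhibitory receptors and phosphatases, the class to which Ptpn6 belongs, 6 rose, 2 fell and 15 did not pass. The adhesion receptor genes Ceacam1 (0.53) and Pecam1 (0.40) rose, and the phosphatase genes Ptpn22 (-1.21) and Ptpn12 (-0.59) fell. Once adjusted over the list alone 6 rose and 4 fell, adding Siglecg (-0.21) and Cd72 (-0.20). The list was not shifted in 1 direction (camera adjusted p = 0.143), with a median of -0.02 below 0 and a mean and camera direction above it, while fry, asked for change in either direction, passed it (adjusted p = 9.70e-07) as 1 of 20 among the 28 lists. Pecam1 did not pass without CRE-ERT2 replicate 1 (adjusted p = 0.0509) or CRE-ERT2 replicate 3 (0.0526).

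Of 18 mature B cell and plasma cell genes, 3 rose, 1 fell and 14 did not pass. Cd74 (1.47), the BAFF receptor gene Tnfrsf13c (0.78) and the chemokine receptor gene Cxcr5 (0.63) rose, and the plasma cell marker Sdc1 (-0.44) fell. Adjusted over the list alone 4 rose and 2 fell, adding Jchain (0.34) and Cr2 (-0.28). The median was 0.03, and camera gave an adjusted p of 0.00883, with adjusted p = 0.252 with an estimated correlation and 0.110 on ranks. Sdc1 did not pass without ERT2 replicate 1 (adjusted p = 0.0959) or CRE-ERT2 replicate 3 (0.0884), and without ERT2 replicate 2 the median of the list was -0.01. Of 23 B-lineage transcription factor genes, 1 rose, Spib (0.62), also when adjusted over the list alone, and Tcf4 had the next lowest p (-0.17). That list was not shifted (camera adjusted p = 0.152), but passed after a further quantile normalization (0.0397) and without ERT2 replicate 2 (0.0458).

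Of the lists fixed as markers of other cell types that a culture could hold, the mature B cell and plasma cell genes were shifted higher. Their camera adjusted p at the preset correlation was 0.00883, as given above. The other 5 lists, of T cell, myeloid, erythroid and megakaryocyte, stromal and natural killer markers, were not shifted. The mean log2 levels of these lists lay between 6.39 and 7.85, below the median of every array. Single markers lay higher. Gfi1b was at 11.68 and 11.27 and Lat at 10.39 and 10.63 in the arrays labelled ERT2 and CRE-ERT2. Both lay above the upper quartile of every array (10.11 to 10.20), and which cells express them was not tested. Of 15 T cell markers 0 passed (camera adjusted p = 0.568), and Lat (0.24) and Cd3d (-0.16) had the lowest p. Of 23 myeloid markers 1 fell, Ly86 (-0.42), and Lyz2 had the next lowest p (-0.22), with a camera adjusted p of 0.618. Of 12 erythroid and megakaryocyte markers 1 fell, the transcription factor gene Gfi1b (-0.41), and Itga2b had the next lowest p (-0.11), with a camera adjusted p of 0.995. Of 19 stromal markers 0 passed, with Postn at -0.08 and Bgn at -0.09 (camera adjusted p = 0.765). Of 12 natural killer cell markers Gzma rose (2.38) and the other 11 did not pass, with Klrk1 at 0.18 (camera adjusted p = 0.305, but 0.0255 with the dimmest genes left out). Counts adjusted over the list alone were the same in these 5 lists. Ly86 did not pass without CRE-ERT2 replicate 1 (adjusted p = 0.0545) or CRE-ERT2 replicate 3 (0.119), and Gfi1b did not pass without CRE-ERT2 replicate 3 (0.0947). Of 18 cytosolic ribosomal protein genes, kept as a sign of RNA quality, 0 passed, also when adjusted over the list alone, with Rps14 at 0.22 and Rpl7 at 0.09. That list was not shifted (camera adjusted p = 0.0740) but passed on ranks (0.0111), with a trended, robust variance (0.0247), without ERT2 replicate 2 (0.0181) and without CRE-ERT2 replicate 3 (0.0320). The sign of the median, the mean and the test disagreed for the T cell, myeloid, erythroid, stromal and natural killer markers and for the NRF2 targets, whose medians lay between -0.02 and 0.01.

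**Figure D3:**
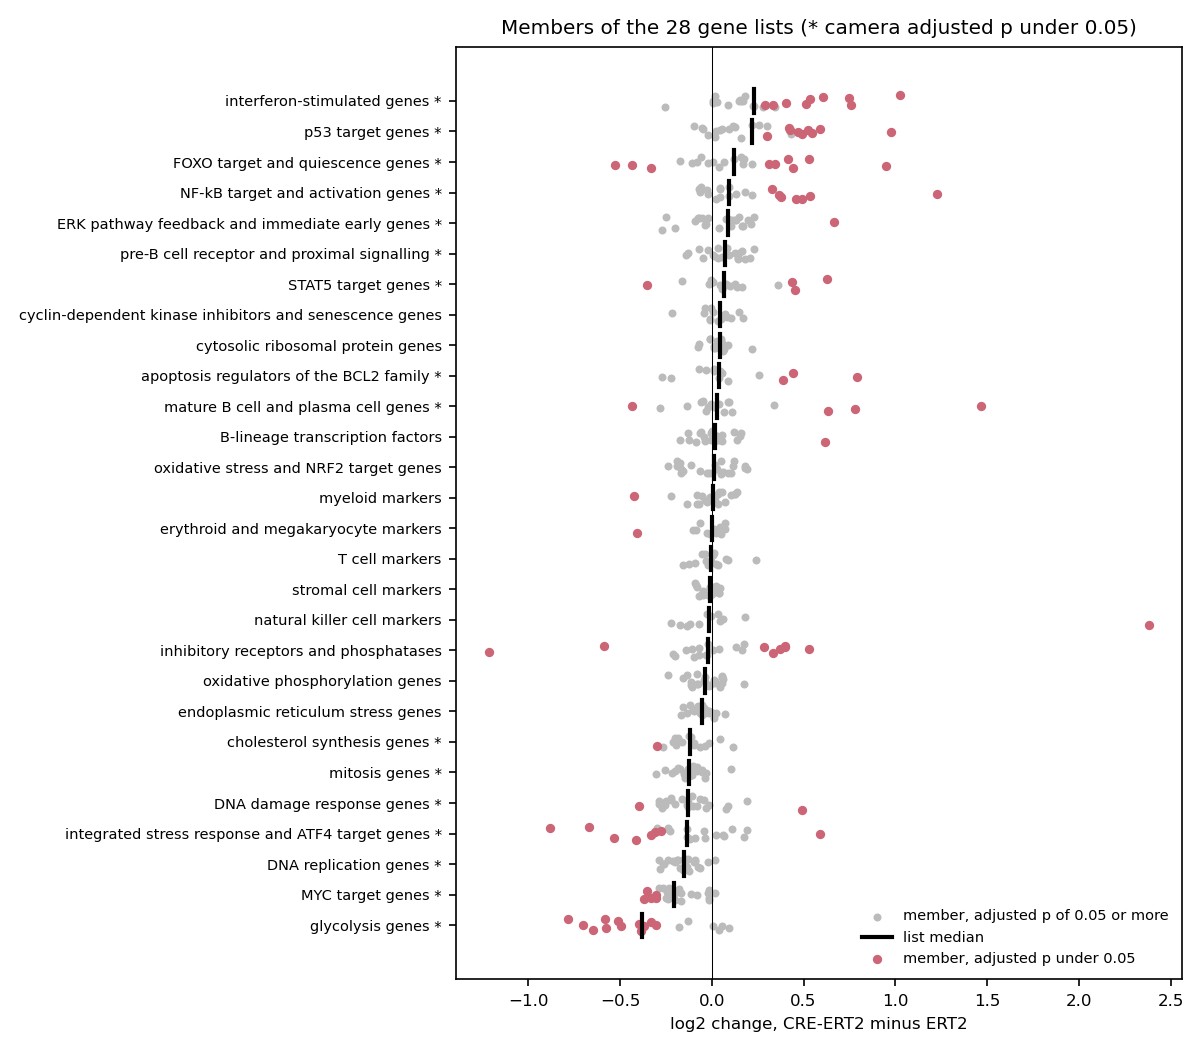
Log2 change (horizontal axis, arrays labelled CRE-ERT2 minus those labelled ERT2) of the measured members of the 28 gene lists (vertical axis, ordered by median), with grey points for members that did not pass, red points for members that passed and black bars for medians. An asterisk marks the 16 lists that passed with camera at its preset correlation, from a median of -0.38 for glycolysis genes to 0.23 for interferon-stimulated genes.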

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

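All tests that weigh an explanation in this part were chosen after the results were seen. Probe sets outside the gene tests also differed between the groups. In a fit over all probe sets, 28 with no gene listed passed an adjusted p of 0.05 (19 higher and 9 lower in the arrays labelled CRE-ERT2), as did 11 that list several genes (7 higher and 4 lower). Single outlying values were not tested for in groups of 3 arrays (array weights ran from 0.680 for ERT2 replicate 1 to 1.63 for CRE-ERT2 replicate 3), and with 1 comparison there was no difference between comparisons to test.

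The first pattern is that 914 genes changed while Ptpn6 did not. Loss of 1 of the 2 Ptpn6 alleles in nearly all cells would put the level near -1 on the log2 scale under certain conditions. These are that the probe set reads the deleted part, that mRNA follows allele number and that the array does not compress the change. If they hold, which was not tested, the lower bound of -0.24 speaks against such a loss. A swap of single arrays between the groups is argued against as well, since the highest count among the other splits of the arrays was 0 genes, and at an unadjusted p under 0.05 the labelled split gave 3260 genes and the highest other 1801. That other split sets ERT2 replicates 1 and 2 and CRE-ERT2 replicate 1 against the rest, and the next, with 1696, sets ERT2 replicates 1 and 3 and CRE-ERT2 replicate 2 against the rest, so some arrays resemble each other across the groups, for a reason that was not tested. It remains open that the probe set lies outside the deleted part, because only 1 Ptpn6 probe set could be compared, and an exchange of the names of both whole groups was not tested. Of the 10 splits of the 6 arrays into 3 and 3, 1, the labelled one, gave as many as 914 genes and the highest other gave 0, and 10 splits are too few for a share under 0.05.

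The next pattern is that p53 target genes and interferon-stimulated genes were both higher as lists, although 16 of 25 and 15 of 24 members did not pass. The 2 lists have 0 genes in common, neither passed with an estimated correlation, and a link between them was not tested. T, natural killer or myeloid cells in the arrays labelled CRE-ERT2 stay open as a source. The median change of their 50 markers was -0.000357 (upper bootstrap bound 0.0259), but 44 of them lay below the median level of all genes, where signal over background is unknown, and they went both ways with an SD of 0.357. Most of that SD came from 1 natural killer marker, Gzma, which had the largest rise of all genes (2.38). Without it the other 49 had an SD of 0.113, less than the interferon-stimulated median of 0.23, and the other 11 natural killer markers had a mean change of -0.04 and did not pass, but leaving out a gene that changed excludes nothing. Another candidate explanation is Cre activity by itself, whatever the Ptpn6 allele, since active Cre can cut DNA, but the design holds 0 arrays of cells with active Cre and no floxed allele, so it cannot be told apart from an effect of the floxed Ptpn6 allele, which also stays open.

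The last pattern is the fall of glycolysis genes (adjusted p = 0.273 with an estimated correlation). A lower share of dividing cells stays open. The glycolysis median was lower than the mitosis median (difference -0.25), by less than the SD of the glycolysis members (0.274). A permutation test over genes gave p = 1e-05, the lowest value that 100000 permutations allow. It treats correlated genes as independent, and whether the 2 lists follow the share of dividing cells equally was not tested, so it cannot decide. Lower activity of HIF, the oxygen-sensing transcription factor, in the arrays labelled CRE-ERT2 may contribute. A list of 28 HIF targets, named as outside glycolysis, still held the glycolysis regulators Pfkfb3 (0.02) and Pfkfb4 (0.02). The list was made after Ak4, Bnip3 and its own members' values were seen and leaves out those 2 genes. Its median was -0.21, and 8 of its members fell while 0 rose (camera unadjusted p = 3.77e-06, but 0.0537 with an estimated correlation). Whether oxygen, culture density, lower MYC or the Ptpn6 allele lies behind it was not tested.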

How the results depend on the processing

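One alternative, leaving out genes that belong to more than 1 list, was chosen after seeing the data, and the others were fixed before. Ptpn6 kept its sign and did not pass under 14 alternatives (-0.12 to -0.04 when single arrays were left out). Against 914 genes (459 higher, 455 lower), 49 passed with a log2 change of at least 1 (31 and 18), by construction a subset. Testing all probe sets gave 298 (188 and 110), of which 254 were among the 914; 22 of the 95 named genes lost their call there, with adjusted p from 0.0577 to 0.232 (Atr, Bmf, Ccl3, Chac1, Cish, Gadd45b, Gfi1b, Lta, Ly86, Mt2, Mvk, Myc, Pecam1, Polr1b, Ppat, Rag2, Sdc1, Sesn2, Shmt1, Socs1, Spib and Zmat3). A trended and robust variance gave 1544, of which 957 were lower, and leaving out the dimmest genes gave 1260, of which 720 were lower; the cause was not tested. Leaving out 1 array gave 453 to 979 genes (286 to 424 higher, 167 to 561 lower), with fewer arrays per fit. A further quantile normalization gave 892 (60.9% higher, against 50.2%), the mean of probe sets 910, centred arrays 922 and array weights 1033.

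Arrays with the same number did not deviate together: the correlations of their deviations from the group means were -0.11, -0.37 and -0.07. Each array correlated best with one of another number, ERT2 replicate 2 with CRE-ERT2 replicate 1 (0.449), ERT2 replicate 3 with CRE-ERT2 replicate 2 (0.396) and ERT2 replicate 1 with CRE-ERT2 replicate 3 (0.180). Over all probe sets the first 2 of these pairs (Pearson r = 0.9951 and 0.9949) were closer than any pair within ERT2 (at most 0.9943). Some structure is thus shared across the groups; its source was not tested. With the replicate number as a block, 589 genes passed (263 lower), all among the 914, and of the named genes Shmt1 (adjusted p = 0.0710), Polr1b (0.0920) and Mvk (0.111) did not.

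Of the 68 named genes that passed, 13 did not pass without at least 1 array, 0 of them among the 24 most changed, and 0 named genes changed sign under any alternative. In 24 cases a named gene gained a call, which concerned 12 genes: Bub1, Cdc6, Gins1, Lss, Pik3cd and Lat under more than 1 alternative, and Blnk, Etv5, Gsr, Lmnb1, Ndufs1 and Sod2 with a trended, robust variance only. Of the gene lists, 16 were shifted (9 higher, 7 lower), but 0 with an estimated correlation (0 higher and 0 lower), and 14 to 16 when 1 array was left out (7 to 11 higher, 5 to 7 lower). List medians near 0 changed sign in 31 cases. The median log2 change of all genes was -0.03 as deposited. It was -0.01 with centred arrays and -0.01 after a further quantile normalization, so this offset itself depends on the processing. Its share in the sign changes was not tested. Reading the sign from the median was chosen after values were seen, in place of the direction of the test, which changed in 21 cases. With the dimmest genes left out, medians were 0.00709 for inhibitory receptors, 0.00347 for T cell, -0.0106 for erythroid and 0.0593 for natural killer markers. With centred arrays they were 0.0126 for T cell, 0.00911 for stromal and 0.00227 for natural killer markers, with array weights 0.00586 for T cell and 0.00655 for natural killer markers, and after quantile normalization 0.0117 for oxidative phosphorylation genes. When 1 array was left out, medians ran from -0.0313 to 0.0398 for inhibitory receptors, -0.00525 to 0.0526 for cyclin-dependent kinase inhibitors, -0.00205 to 0.0216 for B-lineage factors, -0.00932 to 0.0371 for mature B cell genes, -0.000535 to 0.0259 for NRF2 targets and -0.0772 to 0.0105 for oxidative phosphorylation genes. They ran from -0.0556 to 0.0157 for T cell, -0.0586 to 0.0388 for myeloid, -0.0412 to 0.0386 for erythroid, -0.0627 to 0.0165 for stromal and -0.0772 to 0.0326 for natural killer markers. Signal over background is unknown here, which limits what can be said of dim genes.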

Other observations

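All tests in this part were chosen after the results were seen, on 4 gene lists that include the HIF targets. Some targets of HIF, the transcription factor of the response to low oxygen, were lower in the arrays labelled CRE-ERT2. The list of 28 HIF targets, named as outside glycolysis, still held the glycolysis regulators Pfkfb3 and Pfkfb4. Of the 28, 20 did not pass with limma, 0 rose and 8 fell. They were the glycogen branching enzyme gene Gbe1 (log2 change -0.49), the collagen-modifying enzyme genes Plod2 (-0.46) and P4ha1 (-0.43), the oxidoreductase gene Ero1a (-0.46), Ankrd37 (-0.39), the demethylase gene Kdm3a (-0.32), the oxygen sensor gene Egln3 (-0.31) and Fam162a (-0.29). Other targets were near 0 or did not pass, among them Vegfa (-0.25), Pfkfb3 (0.02) and Ddit4 (0.17). The list was shifted with camera (adjusted p = 1.51e-05 over the 4 lists), but not with an estimated correlation (adjusted p = 0.107).

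The metallothionein genes Mt1 and Mt2 and the zinc transporter gene Slc30a4 (-0.31) fell, 3 of 8 genes of metal binding and zinc transport, while Mt3 was -0.01 (camera adjusted p = 0.00103, but 0.101 with an estimated correlation). Of 15 circadian clock genes measured, 3 fell, Ciart (-1.09), Nr1d1 (-0.54) and Nr1d2 (-0.35), and 12 did not pass, among them Per1 (-0.31) and Dbp (0.09). Camera gave an adjusted p of 0.00103 for that list, but 0.159 with an estimated correlation. Of 9 SLAM family receptor genes, Slamf7 (-1.42) and Cd244a (-1.04) fell, and 7 did not pass, among them Slamf6 (-0.14) and Ly9 (-0.04). Camera gave an adjusted p of 0.0430, but 0.159 with an estimated correlation. The metallothionein, clock and SLAM lists were prompted by members that fell, and the HIF list was made after its members' values were seen, so none of the 4 p-values is independent evidence.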
